A study of Mus musculus and Danio rerio with 21 samples.

How the data were processed

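Single-cell transcript counts of satellite cells, the muscle stem cells marked by a nuclear GFP under the Pax7 promoter, and of zebrafish caudal fin cells were analysed in 21 samples, 20 of them from mouse. The mouse samples were 7 CEL-Seq libraries from 3 mice, 8 SORT-Seq libraries from a plate digested for 1 h and a plate digested for 2 h in collagenase, and 5 SORT-Seq plates of cells stained with MitoTracker, a dye taken up by mitochondria. CEL-Seq and SORT-Seq both amplify messenger RNA linearly and sequence its 3' end with a cell barcode and a molecular identifier. The zebrafish sample held 11 plates from 2 fish, named C and E.

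Per the labels and the file headers, the authors deposited unique transcript numbers per gene and well, corrected for molecular identifiers used more than once. These are expected counts in the deposited tables, and they were rounded to whole numbers here before any test. The identifier pool was 256 for CEL-Seq and for the plates of 1 h and 2 h and 4096 for zebrafish, as the steps between the lowest deposited values show, so the most abundant genes of wells with many cells approach saturation. BWA 0.6.2-r126 and the genome builds mm10 and Zv9 are named in the submitters' processing notes, without their roles. The settings of the alignment, the gene annotation and any filter on multiply mapping reads are not given in the sources used here. Per the file headers, the authors also deposited fluorescence and scatter intensity values of the index sort for each MitoTracker-stained cell, and a stress score whose construction is not given in the sources used here. Intensity values were used only to rank cells within a plate, and the deposited score was used only beside shares computed here. Merged versions of the mouse tables were not used. Spike-ins were left out, and mitochondrially encoded transcripts, which only the MitoTracker tables list, were left out of library sizes and kept as a separate share. Zebrafish entries without a gene identifier (1 in all) held 0.00717% of transcripts and were left out, and 11538 of 26778 genes are named by identifier alone.

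Mouse cells with at least 1000 transcripts and fin cells with at least 500 were kept. In SORT-Seq, wells left empty on purpose held a median of 38.0 to 211 transcripts per plate or library. Kept cells per library numbered 4 to 46 in CEL-Seq, 81 to 87 at 1 h, 72 to 83 at 2 h and 29 to 189 per repeat MitoTracker plate. Plates were sorted 1 cell per well, so no doublet caller was run, and occasional wells with more than 1 cell cannot be excluded.

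Counts of kept cells were summed per library, mouse, plate or fish, since cells are not replicates, and were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM scaling, filter on low counts), with levels given as CPM, counts scaled to a common library size, at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were 2 h against 1 h, cells high against cells low in immediate early genes in CEL-Seq, SORT-Seq and fin, and MitoTracker-high against MitoTracker-low cells. High and low cells were the upper and lower tertile of the percentage of a cell's transcripts from the immediate early list, or of MitoTracker intensity, set within each library or plate and, in the fin, within each cluster. The mouse, library, plate or fish was a block in these comparisons, because each gives both classes. The immediate early list counted toward library size and was not tested where it defined the classes. The 4 libraries of a SORT-Seq plate are different cells of the same pool of mice, and the labels do not say whether the plates of 1 h and 2 h shared a pool. Their p-values therefore measure the spread between libraries of a plate and not between mice, and those of the repeat MitoTracker plates the spread between plates, which the labels do not assign to single mice. Each digestion time was 1 plate, so plate and time cannot be told apart.

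Gene lists fixed before the data were examined covered immediate early, heat shock, unfolded protein response, cytokine and NF-kB, p53 and apoptosis, oxidative stress, quiescence, myogenic commitment, cell cycle, glycolysis and hypoxia, nuclear-encoded oxidative phosphorylation, ribosomal protein and extracellular matrix genes, and markers of satellite cells and of other cell types. They were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and again with an estimated correlation, where at least 3 members were tested. Markers of endothelial, immune, muscle fibre, Schwann, tendon and erythroid cells had fewer than 3 tested members in each mouse comparison and were not tested as lists. The rule for named genes, also fixed then, took the 8 largest rises and the 8 largest falls among called genes with a mean of at least 20 CPM and the same direction in each library or pair, the 2 members of each list with the smallest p, and a short set of stress and myogenic genes. The rule covers 190 gene and comparison pairs, of which 129 were carried into the alternative settings and the text after their values were known, mainly by leaving out list members that passed no test; a few of the 129 are not reported here. Genes given outside the rule are marked where they appear.

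Per-cell shares were summarised as the median over cells per library and compared with exact two-sided permutation tests. For the share of cells high in immediate early genes each cell was thinned at random to 1000 transcripts, and the threshold was the 75th percentile of the cells of 1 h. Levels of 2 h and 1 h were also averaged with equal weight over cells with Xist alone and cells with a Y-linked transcript alone, as mean log2 CPM with a prior count of 2, with exact two-sided permutation and sign-flip tests. Rank correlations with MitoTracker intensity were computed within plates and tested by exact sign flips over 4 plates, whose smallest p is 0.13.

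Fin cells were clustered with the stress and ribosomal lists left out (1500 variable genes, 20 principal components, 15 neighbours, Leiden resolution 1.0; igraph 0.11.9, leidenalg 0.10.2, scikit-learn 1.9.0). A cluster took a name only with at least 3 markers of a type fixed beforehand. After the clusters were seen, markers shared by all leukocytes were no longer held against a macrophage name, and the cluster led by immunoglobulin genes was left unnamed. Mouse coordinates come from the GENCODE M21 annotation of mm10, and older symbols without a match there carry none. Zebrafish genes are given by name, with no coordinates.

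Each edgeR and DESeq2 step was tested on counts simulated for the genes of its comparison, with 200 of them changed among the 1000 most abundant (fewer where fewer genes could be tested). The simulated spread followed the trend of spread with abundance and not the spread of each gene. The simulated shares of recovered and false calls therefore may not hold for genes that vary more than that trend. For 2 h against 1 h, edgeR called 100% of the genes changed 2-fold or 4-fold among 6212 tested, and 3.85% of its calls were false. For SORT-Seq high against low cells (3960 genes) it called 100% at both sizes with 3.38% false, and for MitoTracker (4460 genes) 61.0% at 2-fold and 99.0% at 4-fold with 3.61% false. For the fin (7639 genes) it called 42.0% at 2-fold and 100% at 4-fold with 2.74% false. For CEL-Seq (132 genes) it called 0 of 9 genes at 2-fold, where DESeq2 called 3 of 9, and 72.7% of 11 genes at 4-fold. Alternatives were other size factors, DESeq2 1.42.0, no filter on low counts, other minimums of transcripts per cell, thinning, quartiles or a median split, models with or without a block, other clustering resolutions and leaving out each replicate. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.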

Results

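The samples address how the procedure that frees cells from tissue relates to their transcripts. Satellite cells came from the tibialis anterior muscle of mice. For CEL-Seq, male mice named b, c and d of 5 to 7 months gave 4, 2 and 1 libraries after 1 h in collagenase, with 33495 to 204536 transcripts per library. For SORT-Seq, cells labelled as from 4 male mice gave 4 libraries after 1 h (400893 to 454166 transcripts, 338 cells kept) and 4 after 2 h (314958 to 372963 transcripts, 311 cells kept). MitoTracker-stained cells of female mice filled a pilot plate from 1 mouse of 4.7 months (752376 transcripts, 148 cells kept) and 4 repeat plates from 3 mice of 6 months (166474 to 1111698 transcripts, 412 cells kept). The fin table held 2551606 transcripts for fish C, with 925 cells kept, and 1311075 for fish E, with 757 cells kept.

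Of 37 tested immediate early genes, which are transcribed within minutes of a stimulus, 20 fell and 0 rose in edgeR after 2 h of collagenase against 1 h. The list's adjusted p = 0.0706 with an estimated correlation, so its call was lost. Cyr61, a secreted matrix protein, fell from 774 ± 268 to 106 ± 89.4 CPM (SD, n = 4 libraries each), a log2 change of -2.83 (SE 0.323, edgeR adjusted p = 2.42e-06). The transcription factors Egr2 and Atf3 changed by -2.31 and -2.23, the RNA-binding protein gene Zfp36 by -1.83, and Btg2, an antiproliferative gene, by -1.94. Fos fell from 3150 ± 669 to 1840 ± 761 (log2 change -0.77, adjusted p = 0.00864) and Egr1 from 2999 ± 599 to 1445 ± 399 (-1.05), while Jun did not pass the test (-0.56, adjusted p = 0.128). In contrast, the inducible chaperone genes Hspa1a and Hspa1b rose by 0.78 and 0.95, from 1860 ± 310 to 3189 ± 956 and from 1544 ± 148 to 2979 ± 905. They are near-identical copies on chromosome 17 (34969190 to 34972156 and 34956436 to 34959238, minus strand, mm10), so their split is uncertain. Egr1 lies on chromosome 18 (34859823 to 34864984, plus strand), Fos on chromosome 12 (85473890 to 85477273, plus strand) and Atf3 on chromosome 1 (191170296 to 191218039, minus strand).

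Of 6265 genes tested, 42 rose and 76 fell. The immediate early genes had a median log2 change of -0.90; adjusted over the list alone 1 rose and 25 fell, with DESeq2 12 fell, and with thinned cells 6 of 22 fell. With DESeq2 7 of the 20 were no longer called, among them Fos (adjusted p = 0.344) and Atf3 (adjusted p = 0.146), and Klf2 had no adjusted p. The camera adjusted p for the list was 5.46e-45 with the preset correlation. Of 16 cytokine and NF-kB genes 6 fell (7 adjusted over the list alone; adjusted p = 0.126 with an estimated correlation), among them Socs3, on chromosome 11 (117966079 to 117970047, minus strand), a feedback inhibitor of cytokine signalling (-1.58), and Cebpd (-1.35); with DESeq2 3 of the 6 were called, Socs3 not among them (adjusted p = 0.0826), and with thinned cells 1 of 7 tested. Of 21 heat shock genes 2 rose (adjusted over the list alone, 3 rose and 1 fell; adjusted p = 0.503 with an estimated correlation), and Hsp90aa1 stood at 0.023 (adjusted p = 0.970), with a sign that turned when 1 library of either time was left out. Of 12 unfolded protein genes Xbp1 alone fell (-0.58; 2 fell adjusted over the list alone; adjusted p = 0.126 with an estimated correlation).

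Few genes of the other lists passed between the digestion times. The matrix metalloproteinase gene Mmp2 rose from 125 ± 25.3 to 289 ± 32.6 (1.2 on the log2 scale, adjusted p = 2.11e-05), the 1 of 16 extracellular matrix genes that passed (2 rose and 1 fell adjusted over the list alone). Of 12 satellite cell markers, Myf5 (-0.45) and Des (-0.48) fell (5 adjusted over the list alone; adjusted p = 0.0857 with an estimated correlation), whereas Pax7 stood at -0.073 (adjusted p = 0.819) and Myod1 at -0.38 (adjusted p = 0.225). Des was the 1 of 4 myogenic commitment genes, and Myf5 the 1 of 25 quiescence genes, that passed (2 and 3 fell adjusted over the list alone). In edgeR and in DESeq2, 0 of the 76 ribosomal protein, 58 oxidative phosphorylation, 12 glycolysis, 8 oxidative stress, 5 cell cycle and 4 p53 genes passed, with no adjusted p from DESeq2 for 1, 5, 3, 4, 4 and 4 of them. At an unadjusted p under 0.05 these lists held 5, 7, 1, 2, 0 and 0 genes, and adjusted over the list alone 1 oxidative stress gene fell. Other called genes were Casp8ap2 (1.37), Trip11 (1.28), Ttyh1 (1.21), Hlf (1.14), Rrp1b (1.13) and the pseudogene 2610005L07Rik (1.05), and Fam198b (-2.20) and Tbx2 (-1.69).

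Some markers of other cell types differed between the digestion times. Dcn, a matrix proteoglycan of fibroblasts encoded on chromosome 10 (97479609 to 97518143, plus strand), fell from 559 ± 135 to 117 ± 37 (-2.26, adjusted p = 1.78e-08) and Dpt rose from 508 ± 32.5 to 752 ± 90.8 (0.57), so the 3 tested fibro-adipogenic markers split (1 rose, 1 fell, also adjusted over the list alone; adjusted p = 0.20 with an estimated correlation). Of 4 smooth muscle and pericyte markers Acta2 (-0.69) and Tagln (-0.87) fell (the same counts adjusted over the list alone; adjusted p = 0.132 with an estimated correlation), and DESeq2 did not call Tagln (-0.86, adjusted p = 0.0579). Within cells that held a Y-linked transcript and no Xist, Dpt was at -0.16 and Acta2 at 0.17, and within cells with Xist and no Y-linked transcript Acta2 was at -0.11. With DESeq2 29 genes rose and 43 fell, and with each cell thinned to 1000 transcripts 26 genes passed among 1538 tested.

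**Figure D1:**
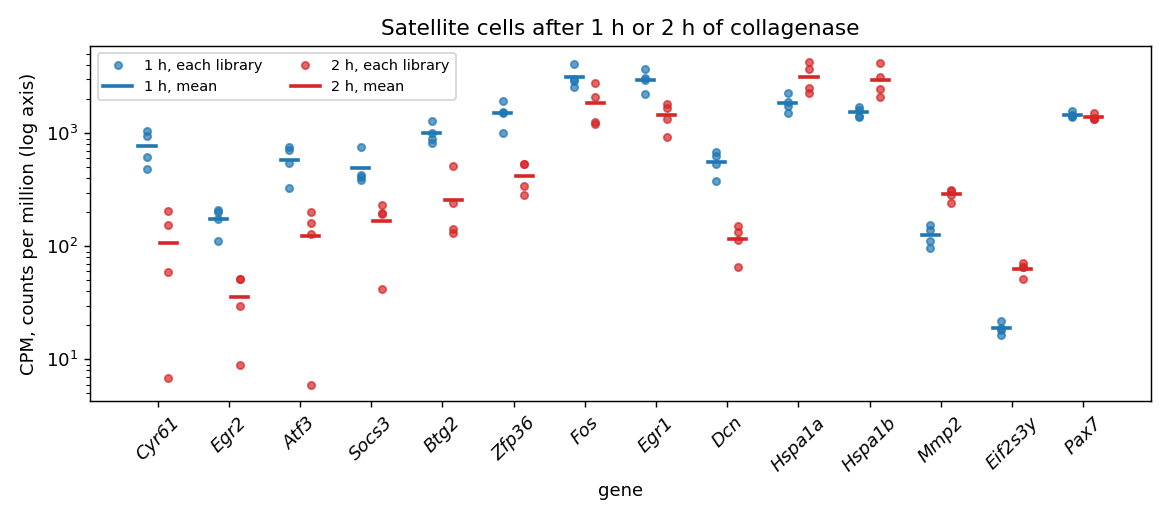
CPM (log axis) of 14 genes in each of the 4 libraries of 1 h (blue) and of 2 h (red), with a line at each mean. Cyr61 averaged 774 at 1 h and 106 at 2 h, and Hspa1a 1860 and 3189.

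Sex-linked transcripts differed between the plates as well. Eif2s3y, a translation factor gene of the Y chromosome (1010543 to 1028847, plus strand, mm10), rose from 18.9 ± 2.26 to 63.5 ± 8.37 CPM (log2 change 1.73, adjusted p = 5.67e-04). Chosen after the values were seen, Ddx3y, also Y-linked, changed by 1.15 (adjusted p = 0.0413), and Xist, the RNA that coats the inactive X chromosome (103460366 to 103483254, minus strand), by -0.97 (adjusted p = 1.41e-04). Of 649 cells, all labelled male, 290 held Xist and no Y-linked transcript, 175 held a Y-linked transcript and no Xist, 17 held both and 167 neither. Among cells with either kind alone, those with a Y-linked transcript made up 18.4% ± 7.96 at 1 h and 61.2% ± 8.75 at 2 h (SD, n = 4, exact two-sided permutation p = 0.0286, the smallest this design allows). Within cells with Xist alone edgeR called 1 gene, Malat1, among 3847 (314 at an unadjusted p under 0.05), and within cells with a Y-linked transcript alone 4 genes, Cyr61, Malat1, Mt2 and Nfkbiz, among 1847 (171 unadjusted). Cyr61 stood at -2.21 (SE 0.514) and -3.50 (SE 0.575) in these kinds of cell, Btg2 at -1.86 (SE 0.434) and -2.40 (SE 0.539), and Egr1 at -1.07 (SE 0.407) and -1.74 (SE 0.484). Hspa1a stood at 0.44 (SE 0.320) and 0.79 (SE 0.360). Of the immediate early genes 0 of 34 and 1 of 22 were called in these fits (17 and 19 at an unadjusted p under 0.05; DESeq2 was not run there). Whether changes differed between the kinds of cell was not tested. Acta2 was at -0.11 (SE 0.194) in cells with Xist and 0.17 (SE 0.511) in cells with a Y-linked transcript, Dpt at 0.50 (SE 0.185) and -0.16 (SE 0.181), and Des at -0.39 (SE 0.156) and 0.092 (SE 0.245). In cells with Xist Dcn was at -1.32 (SE 0.399) and Tagln at -0.41 (SE 0.414).

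**Figure D2:**
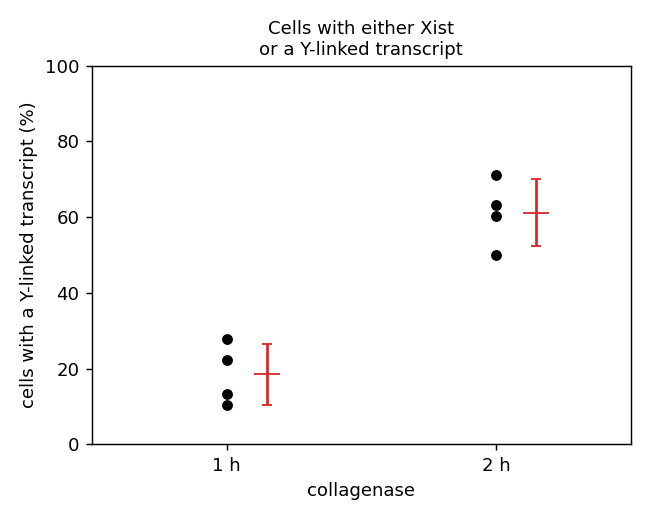
Cells with a Y-linked transcript as a percentage of cells with either Xist or a Y-linked transcript alone, for each library (points), with the mean and SD (red). The libraries of 1 h lie between 10.4% and 27.7%, and those of 2 h between 50% and 71.2%.

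The share of a typical cell's transcripts from immediate early genes was not shown to differ between the times. The median share was 0.504% ± 0.0851 at 1 h and 0.455% ± 0.0524 at 2 h (SD, n = 4, exact two-sided permutation p = 0.40, adjusted p = 0.40 over the 2 lists). For heat shock genes it was 0.717% ± 0.0250 and 0.749% ± 0.0501 (exact p = 0.286, adjusted p = 0.40). In place of the median over cells, the list's share of the summed transcripts of a library's kept cells was also taken, which weights deeper cells more. The difference in this pooled share was -0.924 percentage points for immediate early genes (exact permutation p = 0.0286, adjusted p = 0.0571). For heat shock genes it was 0.320 (exact permutation p = 0.0571, adjusted p = 0.0571). Cells above the 75th percentile of 1 h (1.475% of transcripts after thinning) made up 25.1% ± 3.23 of cells at 1 h and 14.7% ± 4.62 at 2 h, or 85 of 338 and 46 of 311 cells. That difference of -10.5 percentage points had an exact two-sided permutation p = 0.0571 and did not pass 0.05. It passed without thinning (-9.78, exact p = 0.0286) and without the fourth library of 2 h (-12.7, exact p = 0.0286), but not with the threshold at the 50th percentile (-4.79, exact p = 0.229) or the 90th (-5.88, exact p = 0.0571). Cells under the minimum of 1000 transcripts, 38 at 1 h and 65 at 2 h, were left out, and 12 cells lay within 1 transcript of the threshold.

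Within SORT-Seq libraries, 12 of 20 heat shock genes and 13 of 16 cytokine and NF-kB genes were higher in cells high in immediate early genes (adjusted p = 8.35e-04 and adjusted p = 0.00188 with an estimated correlation). Hspa1a stood at 5993 ± 2363 CPM in high cells and 480 ± 225 in low cells (SD, n = 8 libraries), a log2 difference of 3.61 (SE 0.118, edgeR adjusted p = 8.64e-26). Socs3 (4.97), Sbno2 (4.60), Cxcl1 (4.54), Dnajb1 (4.27; chromosome 8, 83608193 to 83612653, plus strand), Nfkbiz (4.20), Cebpd (3.95), Tnfaip6 (3.67) and Hspa1b (3.24) were higher too. Hsp90aa1 rose by 1.75. Adjusted over the list alone, 12 heat shock genes rose and 1 fell, and 15 cytokine genes rose. Of 8 oxidative stress genes 5 rose, among them the metallothionein genes Mt1 (2.19) and Mt2 (2.07), and of 10 unfolded protein genes 4 rose, Hspa5 by 2.16 and Atf4 by 1.49 (adjusted p = 0.00188 and adjusted p = 0.00482 with an estimated correlation; 7 in each adjusted over the list alone). DESeq2 called 11 of the heat shock, 11 of the cytokine, 3 of the oxidative stress and 3 of the unfolded protein genes; with thinned cells 6 of 7 cytokine genes passed and with no block 8 of 9.

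Of 76 ribosomal protein genes 45 fell in the high cells (68 adjusted over the list alone) and none rose, with a median log2 difference of -0.24, as in Rplp0 (-0.39) and Rps12 (-0.33). Their camera call was lost with an estimated correlation (adjusted p = 0.117), DESeq2 called 9 of them, edgeR 14 of 72 with thinned cells, 25 with a median split, 20 of 75 in the libraries of 1 h and 6 of 75 in those of 2 h, and with DESeq2 or other size factors 1 of 76 was positive. Of 57 oxidative phosphorylation genes 3 fell, among them Ndufa13 (-0.64) and Ndufb9 (-0.60) (8 adjusted over the list alone, 0 with DESeq2, 8 there at an unadjusted p under 0.05; adjusted p = 0.00418 with an estimated correlation). Their count was 1 at 1 h, 0 at 2 h (5 unadjusted) and 7 either at 2000 transcripts or with quartiles, and 0 of 17 with thinned cells (0 unadjusted). The quiescence list went both ways (4 rose, 1 fell of 25), with Hes1 at 1.04 and Spry1 at 0.63, and so did satellite markers (2 rose, 1 fell of 12), with Des at 0.58, Pax7 at 0.13 (adjusted p = 0.419) and Myf5 at 0.13 (adjusted p = 0.522). The counts adjusted over the list alone were 4 and 1 for quiescence and 2 and 3 for satellite markers. Myogenic commitment (Des rose of 4, with Myod1 at -0.46 and an adjusted p = 0.0580), cell cycle (Pcna 0.84 and Ccnd1 -1.23 of 4), glycolysis (1 rose, 1 fell of 11, Gapdh -0.28), extracellular matrix (1 rose, 1 fell of 16, Sparc -0.49) and p53 genes (1 rose of 3) had few calls; adjusted over the list alone, 1 myogenic gene also fell and the other counts stayed as given. DESeq2 called 3 of the 5 quiescence genes and neither Ccnd1 (adjusted p = 0.113) nor Gapdh (adjusted p = 0.368).

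Over all 4193 tested genes 219 were higher and 133 lower in the high cells, and with DESeq2 136 and 23. Acta2, a smooth muscle actin, fell by 1.15, and of the smooth muscle and fibro-adipogenic lists 1 of 3 each fell (1 and 2 adjusted over the list alone; adjusted p = 0.204 and adjusted p = 0.373 with an estimated correlation). The fibro-adipogenic gene, Col3a1, was not called with DESeq2 (adjusted p = 0.331). Other falls were Mgl2 (-1.66), 2810008D09Rik (-1.55), H2-Ke6 (-1.18), C1qtnf3 (-1.13) and Uqcr11 (-1.04). The libraries of 1 h alone gave 223 genes and those of 2 h alone 86. Thinned cells gave 67 of 631.

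**Figure D3:**
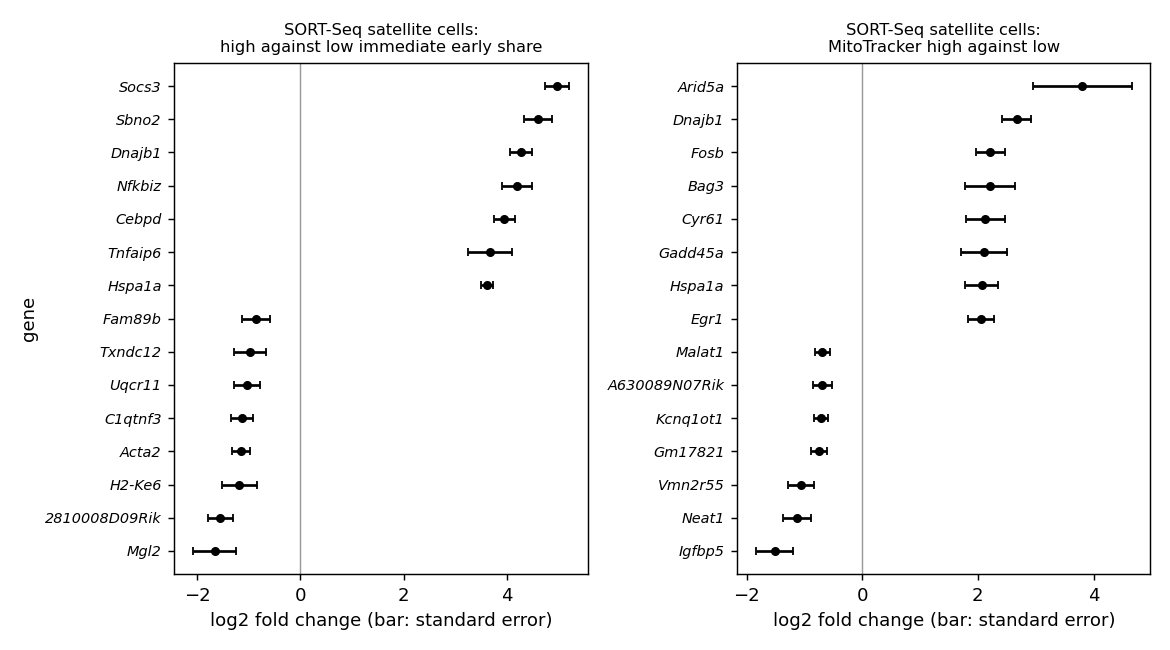
Log2 fold change with its standard error for genes among those with the largest rises and falls, in cells high against low in immediate early genes (left) and MitoTracker-high against MitoTracker-low cells (right). Socs3 stands at 4.97 on the left and Arid5a at 3.80 on the right.

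In CEL-Seq, 7 of the 8 heat shock genes that passed the filter on low counts were higher in cells high in immediate early genes. The list's call was lost with an estimated correlation (adjusted p = 0.158). The filter left 8 of 23 list members, and Hsp90aa1 and Dnajb1, with 0 CPM in low cells of mice c and d, passed it mainly through the high cells. With no filter edgeR called 5 of 22 tested heat shock genes (11 at an unadjusted p under 0.05). Hspa1a stood at 16677 ± 8952 CPM in high cells and 2409 ± 2169 in low cells (SD, n = 3 mice; log2 difference 2.76, edgeR adjusted p = 3.83e-04). Dnajb1 (3.34), Hsp90aa1 (2.85), Hspb1 (2.26), Mt1 (2.75), Mt2 (2.72) and Cebpd (2.59) were higher, and the ribosomal gene Rpl28 was lower (-1.14). Of 126 tested genes 12 rose and 1 fell, including 1 of 68 ribosomal protein genes (adjusted p = 0.158 with an estimated correlation). Adjusted over the list alone 7 heat shock and 0 ribosomal protein genes passed. Of 3 quiescence genes 0 passed in edgeR, in DESeq2, adjusted over the list alone or at an unadjusted p under 0.05, with Spry1 at 0.23 (adjusted p = 0.709). Mouse d gave 1 cell per class, and the count was 1 of 69 tested genes without mouse b and 22 without mouse d. With no block 6 genes passed. Of the heat shock genes edgeR called 0 of 3 tested without mouse b (2 at an unadjusted p under 0.05; DESeq2 was not run there) and 3 of 5 with no block, 4 of 7 with a median split, and at 500 transcripts 4 of 7 without mouse b and 2 of 10 without mouse c. DESeq2 called 5 of 8 heat shock genes and 0 of 68 ribosomal protein genes (6 in edgeR at an unadjusted p under 0.05).

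CEL-Seq plates also held wells with many cells lysed together. Their immediate early share was 2.58% ± 0.206 and that of the summed single cells 4.41% ± 1.90 (SD, n = 3 mice). The difference of -1.83 percentage points had an exact sign-flip permutation p = 0.5, where the smallest possible is 0.25, and bulk wells were lower in 2 of 3 mice. Taking all single-cell wells, whatever their depth, turned the difference to 0.185. Up to 72 genes per bulk well lay at 700 or more transcripts, near saturation of the identifiers, with a maximum of 1597.

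In counts summed over cells, 16 of 37 immediate early and 10 of 21 heat shock genes were higher in MitoTracker-high than in MitoTracker-low cells. Both list calls were lost with an estimated correlation (adjusted p = 0.223 for both). Repeat cells were sorted through a low gate, P11, with MitoTracker intensity up to 8376, and a high gate, P12, with a median of 35924.5. Cells in neither gate reached 13124. The median intensity of the MitoTracker-low cells was 18498 in plate 3, so most of these came from P12. It was 4209 to 6686 in the other plates. Dnajb1 stood at 1349 ± 493 against 210 ± 129 CPM (SD, n = 4 plates; log2 difference 2.67, edgeR adjusted p = 1.55e-07) and Egr1 at 3092 ± 689 against 734 ± 333 (2.05). Fosb (2.22), Bag3 (2.21), Cyr61 (2.13), Gadd45a (2.1), Hspa1a (2.07), Cebpd (1.97), Hspa1b (1.92), Fos (1.90), Hsp90aa1 (1.04) and Jun (0.85) were higher, and Arid5a stood at 3.80 from a level of 3.10 ± 6.20. Atf3 (1.56, adjusted p = 0.173) and Socs3 (1.45, adjusted p = 0.128) did not pass. Lower genes included the nuclear RNAs Neat1 (-1.13), Kcnq1ot1 (-0.71) and Malat1 (-0.69; chromosome 19, 5795690 to 5802672, minus strand), and Igfbp5 (-1.51), Vmn2r55 (-1.05) and the pseudogene Gm17821 (-0.74). Reads of that pseudogene and of Kcnq1ot1, which is antisense to a coding gene, cannot be assigned with certainty.

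Adjusted over the list alone 21 immediate early and 14 heat shock genes rose. Without plates 1, 2, 3 and 4 edgeR called 7, 6, 19 and 10 of the immediate early genes and 4, 4, 9 and 6 of the heat shock genes, and with thinned cells 5 of 18 and 5 of 12. With no block the counts were 8 and 7, at 2000 transcripts 10 and 6, with quartiles 7 and 6, and with intensity freed of forward scatter 8 and 5. DESeq2 called 8 and 7 and gave no adjusted p for the other 8 and 3 that edgeR called. Of 74 ribosomal protein genes 8 rose (56 adjusted over the list alone), with Rplp0 at 0.71 and Rplp1 at 0.57, and 2 of 12 cytokine genes rose (5 adjusted over the list alone; adjusted p = 0.246 for both with an estimated correlation). Without plates 1, 2, 3 and 4 edgeR called 0, 0, 9 and 1 of the ribosomal genes (45, 37, 55 and 52 at an unadjusted p under 0.05), and with thinned cells 0 of 69 (18 unadjusted). Their count was 37 at 500 transcripts, 31 of 80 with no filter, 10 with DESeq2, 5 between the sort gates, 3 with other size factors, 1 each with no block, at 2000 transcripts and with quartiles, and 0 with intensity freed of forward scatter (53 unadjusted). The cytokine count was 0 without plate 1, 2 or 4 (4, 3 and 5 unadjusted), at 2000 transcripts and with quartiles (5 each), and 5 of 13 between the gates. Of 6 myogenic commitment genes 3 rose, among them the differentiation factor Myog (3.63) and the fusion gene Tmem8c (3.00), and of 17 cell cycle genes Top2a fell (-2.46) while Mki67 stood at -1.73 (adjusted p = 0.116); adjusted over the list alone 3 rose and 4 fell (adjusted p = 0.246 and adjusted p = 0.260 with an estimated correlation). Of 24 quiescence genes 1 was called, also adjusted over the list alone, the growth inhibitor Cdkn1c (2.63). The calls of these genes rest on a few plates and did not go the same way in all 4. Myog was at 394 ± 595 and Tmem8c at 230 ± 328 in high cells and Top2a at 628 ± 902 in low cells. Cdkn1c was at 668 ± 1189 in high cells, with 2448 in plate 4, which had 9 cells per class, and 12.4 to 183 in the others. Without plate 4 Myog, Tmem8c and Cdkn1c did not pass the filter on low counts, and Top2a was not called. DESeq2 called 0 of the cytokine, myogenic commitment, cell cycle and quiescence genes and gave no adjusted p for the 2, 3, 1 and 1 that edgeR called (5, 3, 7 and 2 in edgeR at an unadjusted p under 0.05). Pax7 (-0.010, adjusted p = 0.996) and Myod1 (0.0059, adjusted p = 0.999) changed sign between settings, and Myf5 stood at -0.36 (adjusted p = 0.808). In edgeR and in DESeq2, 0 of 59 oxidative phosphorylation, 17 extracellular matrix, 12 satellite, 12 unfolded protein, 11 glycolysis, 6 oxidative stress, 3 p53 and 3 fibro-adipogenic genes passed, but DESeq2 gave no adjusted p for 55, 16, 6, 11, 9, 3, 3 and 2 of them. At an unadjusted p under 0.05 these lists held 1, 3, 1, 1, 1, 1, 0 and 1 genes; adjusted over the list alone 1 unfolded protein and 1 oxidative stress gene rose and 1 matrix gene fell.

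Over 4563 genes 47 were higher and 9 lower. High cells held a median of 6943 ± 1455 transcripts and low cells 2921 ± 788. Forward scatter was 169279 ± 3065 in high and 125019 ± 11884 in low cells, larger in 4 of 4 plates (exact sign-flip p = 0.13). With each cell thinned to 1000 transcripts 13 genes were higher and 18 lower among 632. Without single plates the count ranged from 14 to 99: it was 14, 15, 99 and 21 without plates 1, 2, 3 and 4. Sort values of the pilot cells were joined by cell number, which disagrees with the well for 86 cells, so all pilot values rest on an uncertain join. In the pilot plate, which has no replicate, 42 of 53 called genes had the same direction. There the log2 ratio was 3.29 for Fosb and 1.38 for Egr1, but Cyr61 (-0.61) and Bag3 (-0.60) went the other way, as did Gm17821 (0.35), Vmn2r55 (0.27) and Kcnq1ot1 (0.17). Malat1 was at -0.48, Neat1 at -0.089 and Igfbp5 at -0.051.

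Across cells within plates, the rank correlation of MitoTracker intensity with the heat shock share was positive in 4 of 4 plates, with a mean of 0.312 (SD 0.0732) over plates and 0.305 in the pilot. With the immediate early share it was 0.0728 (SD 0.0820), positive in 3 of 4 plates, and with the mitochondrially encoded share -0.152 (SD 0.138), negative in 4 of 4. Exact two-sided sign-flip p-values were 0.13, 0.25 and 0.13 (adjusted 0.188, 0.25 and 0.188), and with 4 plates the smallest possible is 0.13. With total transcripts held constant the mitochondrially encoded correlation was -0.0389 (exact p = 0.63) and with nuclear transcripts held constant -0.0969; without plate 2 it was -0.0841, and that with the immediate early share 0.0428. The median heat shock share was 1.12% ± 0.312 in high and 0.637% ± 0.0850 in low cells (n = 4, exact p = 0.13). For immediate early genes it was 0.547% ± 0.197 and 0.481% ± 0.0942, higher in 2 of 4 plates (exact p = 0.63), so a typical cell was not shown to differ. The summed share of Malat1, Neat1 and Kcnq1ot1 was 0.750% ± 0.258 in high and 1.56% ± 0.580 in low cells (exact p = 0.13).

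In the fin, mesenchymal-like cells, named from collagen, twist and related genes, had the highest immediate early share in both fish. Their median was 4.70% in fish C (148 cells) and 4.67% in fish E (213 cells), against 0.836% and 0.975% in the other cells. Osteoblast-like cells had 4.12% in fish C (31 cells) and 1.81% in fish E (25 cells). T cell-like cells had immediate early shares of 1.21% and 1.53% and heat shock shares of 1.22% and 1.75%. Other cells had heat shock shares of 0.910% and 0.624%, but these include the unnamed clusters, at 0.167% and 0.130%. In fish C macrophage-like (1.27%), mesenchymal-like (1.25%) and osteoblast-like cells (1.23%) were as high as T cell-like cells, with superficial epithelial-like cells at 1.16%. In fish E these other classes had heat shock shares of 0.791% to 1.43%. Macrophage-like cells had immediate early shares of 1.30% and 1.69%, and basal epithelial-like cells 1.51% and 1.37%. Superficial epithelial-like cells lay below the other cells in fish C by a difference of -0.260 and above them in fish E by 0.843 percentage points, and only 24 of them came from fish E. Cells in unnamed clusters (328 and 276) had 0.347% and 0.301%. With 2 fish no test between classes was made, and these names were rebuilt here from markers.

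**Figure D4:**
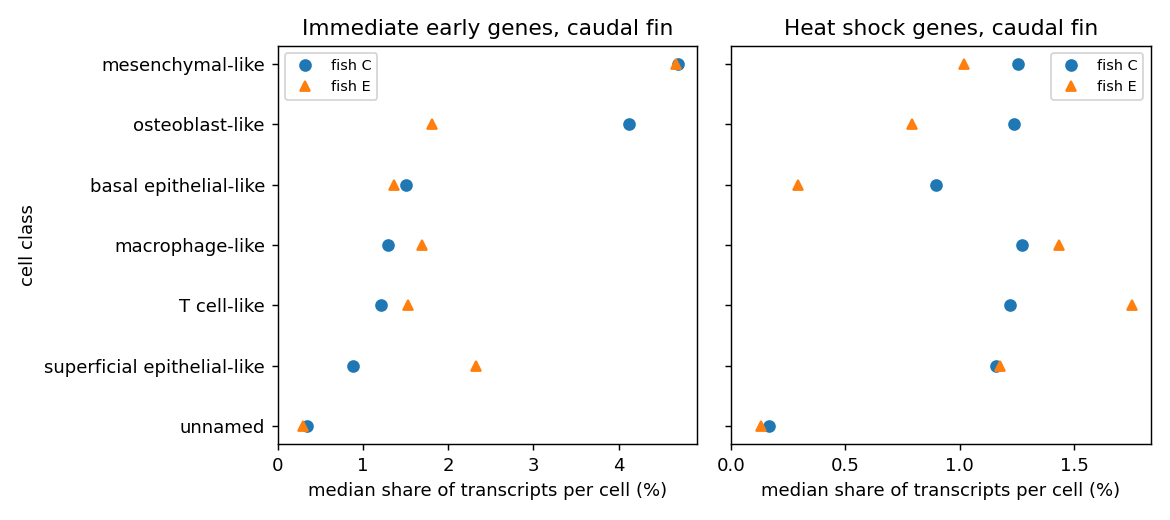
Median percentage of a cell's transcripts from immediate early (left) and heat shock (right) genes by cell class in fish C (circles) and fish E (triangles), for classes with at least 10 cells in each fish. Mesenchymal-like cells stand at 4.70% and 4.67% for immediate early genes.

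Within fin clusters, cells high in immediate early genes were also higher in hsp70l, an inducible chaperone gene (3156 ± 890 against 372 ± 294 CPM, SD, n = 2 fish; log2 difference 3.26, edgeR adjusted p = 9.15e-07). The transcription factor gene jdp2b (3.75), csrnp1b (2.93), spry4 (2.66), rgs5b (2.62), socs3a (2.57), bag3 (2.04), cebpd (1.84), ddit3 (1.24) and atf4b (0.77) were higher, and hspa8 stood at -0.049 (adjusted p = 0.928). The cell cycle genes pcna (-1.62) and rrm1 (-1.55) were lower, as were dpp4 (-3.36), commd1 (-3.61), GSG2 (-4.59) and the immunoglobulin gene ighv1-4 (-5.65), whose levels in low cells differed widely between the fish (607 ± 853). Among these genes, rgs5b was a leading gene of a mesenchymal-like cluster, commd1 of an unnamed cluster and ighv1-4 of the unnamed immunoglobulin cluster. Their differences within clusters may therefore not be separate from cell identity. Of 18 cytokine genes 7 rose, of 18 heat shock genes 4, of 16 unfolded protein genes 2, and of 5 cell cycle genes 2 fell. Adjusted over the list alone 13, 5 and 5 rose and 5 fell, with 2 heat shock genes falling, and each camera call was lost with an estimated correlation (adjusted p = 0.425). The median of the heat shock list was -0.018, although its camera test and mean (0.43) pointed up. DESeq2 called 3 of the cytokine, 3 of the heat shock, 1 of the unfolded protein and 1 of the cell cycle genes, but neither atf4b (adjusted p = 0.374) nor rrm1 (adjusted p = 0.512). With thinned cells edgeR called 1 of 14 cytokine and 0 of 12 heat shock genes (3 unadjusted).

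Of 66 fin ribosomal protein genes 0 passed in edgeR, adjusted over the list alone or in DESeq2 (10 at an unadjusted p under 0.05), with a median of -0.28, and rps23 stood at -1.08 (adjusted p = 0.0819) and at 0.84 with tertiles set within plates alone. Among marker lists col10a1a of the osteoblast list was higher (1.18) and coro1a of the macrophage list lower (-1.09) in edgeR, but DESeq2 called neither (adjusted p = 0.0945 and adjusted p = 0.378), and 0 of 14 mesenchymal, 10 T cell, 9 basal and 8 superficial epithelial markers passed in edgeR and in DESeq2 (5, 2, 4 and 3 at an unadjusted p under 0.05; no adjusted p from DESeq2 for 3, 4, 1 and 2). Adjusted over the list alone, 1 osteoblast marker rose, 3 macrophage markers fell, 4 basal markers rose, and 1 superficial marker rose and 1 fell. Of 7899 genes 93 were higher and 33 lower, and 34 and 3 with DESeq2. The fit had 1 residual degree of freedom, and with no block edgeR called 0 genes (76 at an unadjusted p under 0.05).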

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

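The tests on sex-linked genes and on the sexes of single cells were chosen after the rise of Eif2s3y was seen, and the fits within cells with Xist or with a Y-linked transcript, the levels averaged over these kinds of cell and the correlations holding nuclear transcripts constant were added after the data were seen.

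A total of 14 of 161 groups of 4 to 10 values held a value far from the others, where chance gives about 1 in 20. At 1 h, the fourth library stood at 7.06 CPM for Casp8ap2 (others 20.8 to 21.9) and 28.2 for Trip11 (others 18.2 to 19.5), the second at 761 for Socs3 (others 386 to 432) and the third at 565 for Hspa5 (others 732 to 761). At 2 h the third library had 1518 for Pax7 (others 1331 to 1360). In MitoTracker-low cells plate 1 had 12.4 for Arid5a, where the other plates had 0. Plate 4, with 9 cells per class, had 1225 for Fos (others 709 to 740), 111 for Cdkn1c (others 19.9 to 28.9) and 1968 for Top2a (others 12.4 to 306). In its high cells Cdkn1c was at 2448 (others 12.4 to 183) and Myod1 at 1329 (others 366 to 454), and in plate 2 Rplp0 was at 6584 (others 5041 to 5128). The first CEL-Seq library of mouse b held 204536 transcripts (others 48434 to 74092), and the rank correlation with the mitochondrially encoded share was -0.356 in plate 2 (others -0.105 to -0.0536). Ccnl1, a cyclin gene chosen by its test, differed between high and low cells by 2.02 at 1 h and by 0.50 at 2 h, a difference of -1.51 (SE 0.299, edgeR interaction adjusted p = 0.0346), the 1 call among 4193 genes (215 at an unadjusted p under 0.05).

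At 2 h 20 of 37 immediate early genes were lower in edgeR (12 with DESeq2; adjusted p = 0.0706 with an estimated correlation), and Hspa1a and Hspa1b were higher. Other groupings of the 8 libraries reached at most 7 genes against 118, and 1 of 35, the real one, reached as many. A random split of these libraries is therefore excluded as the source of the count. With 1 plate per time, a chance difference between the plates or their pools of mice is not excluded. Thinned changes kept a median ratio of 0.922 (0.872 to 0.964, 70 of 118 genes). Greater weight of deeper cells in the sums is therefore argued against for those 70 genes. Thinning keeps the expected proportions of each cell, so the ratio cannot decide whether depth affects them. Depth stays open as a cause. A different mix of male and female cells is argued against for the lower immediate early genes but not excluded: the list's median was -0.68 in cells with Xist alone (30 of 34 genes negative, 0 called in edgeR; -1.04 to -0.49 without each library, across the bound of -0.50 set beforehand) and -1.55 in cells with a Y-linked transcript alone (22 of 22 negative, 1 called; -1.95 to -0.97). Averaged over both kinds the list differed by -1.04 in mean log2 CPM (-0.98 in all cells). Xist cells lay below Y-linked ones by a difference of -0.28 (SD 1.03, n = 8) where a mix alone needs at least the whole change. However, the exact permutation and sign-flip p-values, 0.0571 and 0.0312 (this one tried after the other was known), were both 0.0571 when adjusted. For Hspa1a and Hspa1b the difference was 0.11 in Xist cells (exact permutation p = 0.83) and 1.05 in Y-linked cells (exact permutation p = 0.11). Their average of 0.58 (exact permutation p = 0.20) leaves a mix of the sexes open. Cells of another type stay open, since only 2 of 8 marker lists could be tested (medians -0.45 and -0.0041), and the digestion time itself, the biological difference in the design, cannot be told apart from the plate or the mice.

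In the repeat plates, 16 of 37 immediate early and 10 of 21 heat shock genes were higher in MitoTracker-high cells (edgeR; adjusted p = 0.223 for both lists with an estimated correlation), and Neat1, Malat1 and Kcnq1ot1 were lower, of which Kcnq1ot1 went the other way in the pilot. The calls of lower genes depended on the setting. With the higher minimum of transcripts per cell 0 genes were called lower, and 0 with intensity freed of forward scatter. DESeq2 called 8 genes lower, and edgeR 18 with thinned cells. More transcripts per cell in the high class stay open as a cause. Thinned changes of all called genes kept a median ratio of 0.681 (0.496 to 0.767, 45 of 56 genes), between the bounds set for either reading. Thinning evens the weight of cells and keeps their expected proportions. The lower ratio can therefore come from deeper cells within a class weighing more in the sums, and it cannot decide the question. The median log2 difference of the immediate early list was 1.15, and 0.43 with thinned cells, where 18 of its genes were tested. For the heat shock list it was 1.04, and 0.58 with thinned cells, where 12 were tested. For the weak correlation with the immediate early share, holding total transcripts constant gave 1.2 times (0.952 to 1.31 without single plates) and holding nuclear transcripts constant 0.944 times (0.849 to 1.15) the plain value. Both lie above the bound of 0.8 set to exclude them, but that bound was ill chosen, because that value (0.0728) is itself below its SD over plates (0.0820). Of the 8 swaps of class within plates 1 reached the real 56 genes and the highest other gave 22, too few swaps for a share under 0.05. No biological explanation was tested.

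Eif2s3y was higher at 2 h on plates labelled male. Cells of both sexes on the plates are a candidate explanation: Xist and Y-linked transcripts avoided each other, with 17 cells holding both where 68.2 would if independent and a Mantel-Haenszel odds ratio of 0.0635. A larger share of male cells at 2 h is in line with Ddx3y, the 1 other Y-linked gene tested, at 1.15 (0.85 to 1.46). Transcripts assigned instead to the X-linked copy Eif2s3x stay open for Eif2s3y, since Eif2s3x stood at -0.19 (-0.39 to 0.01). Such an assignment predicts no change of Ddx3y or Xist. Within cells with a Y-linked transcript and no Xist, Eif2s3y stood at 0.28 (SE 0.312, edgeR adjusted p = 0.853). Eif2s3y is among the genes that define those cells, so that value cannot decide the question. Whether female cells came from the mice, from handling or from a label is untested, and sex was not a group of this design.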

How the results depend on the processing

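The fits within cells with Xist or a Y-linked transcript alone, the fits of CEL-Seq without single mice at 500 transcripts, the sort gates, thinning of the shares of 2 h and 1 h, of fin cells and of correlations, and correlations holding nuclear transcripts constant were added after the data were seen. Of 187 alternative values of the main results 141 stayed on the same side, 41 moved, 2 became stronger and 3 reversed; causes were not tested except where fewer genes, cells or samples entered.

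For 2 h against 1 h (118 genes) DESeq2 gave 72, no filter 190, thinning 26, Xist cells 1 and Y-linked cells 4, and leaving out a library 88 to 127. The library number as a replicate block gave 142; the numbers do not pair libraries, since same-numbered ones correlated at 0.0228, -0.0287, 0.0324 and 0.0337 and not every one was closest to its own number. The block leaves the mean differences in shares (-0.0490, 0.0322 and -10.5) as they are by construction; its exact sign-flip p-values were 0.5, 0.25 and 0.13, where 0.13 is the smallest possible. The share of high cells was -9.78 without thinning and -12.7 to -9.29 without single libraries. It was -4.79 and -5.88 with the 50th and 90th percentile, and it passed without the fourth library of 2 h. Median share differences without single libraries, which did not pass, were -0.0747 to -0.00777 for immediate early (lowest in size without the second library of 1 h) and 0.0210 to 0.0566 for heat shock genes.

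For CEL-Seq (13 genes) no replicate block gave 6, a median split 8, leaving out a mouse 1 to 22, and at 500 transcripts 4 to 24; a minimum of 2000 could not be fitted. For SORT-Seq (352) DESeq2 gave 159, thinning 67, 1 h alone 223, 2 h alone 86 and no replicate block 236. For MitoTracker (56) no filter gave 105, no replicate block 23, 2000 transcripts 20, thinning 31, quartiles 24, intensity freed of forward scatter 20, and leaving out a plate 14 to 99. For the fin (126) other size factors gave 82, DESeq2 37, no replicate block 0 in edgeR (76 unadjusted), thinning 3, quartiles 54 and tertiles within plates alone, which mix cell classes, 3458. Bulk wells minus all single wells gave 0.185.

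Mean differences of fin classes over the fish moved: macrophage-like immediate early 0.129 at the lower resolution, -0.123 at 250 and -0.170 at 1000 transcripts; mesenchymal-like immediate early 3.58, 4.36 and, thinned, 3.55, and heat shock 0.432 and 0.501; superficial heat shock 0.272 at the higher resolution, 0.411, 0.218 and, thinned, 0.400. Others moved by over 1.5 times but within the spread between the fish: basal immediate early (0.158) to 0.0271 at the higher and 0.306 at the lower resolution, 0.457 at 250 and 0.0682 at 1000 transcripts, and heat shock (-0.340) to -0.20 thinned; T cell-like immediate early (0.126) to 0.195 and 0.0411; osteoblast-like heat shock (0.0864) to 0.143 and 0.0331.

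Of the genes carried into the settings, 8 of 530 values reversed for 2 h against 1 h, 1 of 137 in CEL-Seq, 0 of 363 in SORT-Seq, 15 of 445 for MitoTracker and 4 of 189 in the fin. In Y-linked cells Des was at 0.092, Acta2 0.17, Dpt -0.16, Pax7 0.018 and Hsp90aa1 -0.20; Hsp90aa1 was at -0.091 in Xist cells and -0.073 and -0.11 without the third library of 1 h or the fourth of 2 h. Rpl28 was at 0.11 at 500 transcripts without mouse b, with -1.17 to 0.11 without single mice at either minimum. Against MitoTracker, Pax7 was at 0.074 with no filter, 0.021 at 2000 transcripts, 0.11 with a median split, 0.22 between the gates and -0.25 to 0.12 without single plates. Myod1 was at -0.045 with other size factors, -0.033 with DESeq2, -0.098 at 500 transcripts, -0.058 thinned, -0.18 between the gates and -0.17 to 0.26 without single plates. In the fin hspa8 was at 0.0044 at 250 transcripts, 0.059 thinned and 1.81 with tertiles within plates, where rps23 was at 0.84. At the depth of CEL-Seq 126 genes passed the filter on low counts.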

Other observations

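The comparison of pilot joins, the correlation between CEL-Seq and digestion changes and the marker test of SORT-Seq cells were set before their results, and the values of sex-linked genes outside the plates of 1 h and 2 h and of the deposited stress score were looked at after the data were seen.

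Male CEL-Seq mice b, c and d had 73.7, 134 and 185 CPM of Eif2s3y and 147, 165 and 226 of Ddx3y over all cells. The plates labelled male had 17.5 and 63 of Eif2s3y at 1 h and 2 h and 487 and 251 of Xist. The female pilot and repeat MitoTracker plates had 558 and 362 of Xist.

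The deposited stress score followed the shares computed here within each MitoTracker plate. Across 14 to 134 cells per plate its rank correlation was 0.756 to 0.938 with the immediate early share and 0.765 to 0.883 with the heat shock share, and -0.152 to 0.242 with MitoTracker intensity. These are descriptions over cells, which are not replicates.

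The genes that go with immediate early genes from cell to cell in CEL-Seq were not shown to rise with longer digestion: the rank correlation of the 2 sets of log2 changes over 126 genes was -0.0496 (-0.245 to 0.137), with an interval that reaches past the bound of 0.1. Between CEL-Seq and SORT-Seq high against low cells it was 0.443 over 126 genes, which are not independent replicates. Between SORT-Seq high against low cells and MitoTracker-high against MitoTracker-low cells it was -0.0263 over 3601 genes. Cells of another type among SORT-Seq high cells were tested with 2 of 8 marker lists, and the higher median was -0.38, too few lists to decide. Of the swaps of class within SORT-Seq libraries 1 of 100 drawn, the real one, reached 352 genes and the highest other 159. These swaps exchange the whole high and low classes of a library, so they show that the differences went the same way across libraries. The classes were set from the same counts. The swaps therefore cannot decide whether a split on such a share gives calls by itself. In CEL-Seq 1 of 4 swaps, the real one, reached 13 genes and the highest other 0, too few swaps for a share under 0.05. For 84 pilot cells whose number and well disagree in the index table, the correlation of MitoTracker with total transcripts was higher by 0.131 when joined by well, between the bounds set for either reading.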
